A study of Mus musculus with 28 samples.

How the data were processed

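The data were mRNA profiles of mouse embryonic stem (ES) cells on 28 Affymetrix Mouse Gene ST arrays, each hybridised with labelled cDNA from total RNA of 1 sample. Per the labels' protocols, RNA was prepared with the Qiagen miRNeasy kit and labelled with the Ambion WT expression kit. The deposited values are log2 expression values per probe set, which the submitters' processing notes credit to RMA (robust multi-array average, which corrects background, normalises between arrays and summarises probes) and to Partek 6.6. The settings of these tools are not given in the sources used here, and no scanner files were used here. The deposited table held 35556 probe sets, and array medians lay between 7.13 and 7.26 on the log2 scale.

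Probe sets were named from the platform annotation table, in which 21789 had 1 gene symbol, 1621 had several and 12146 had none. Only probe sets with 1 symbol were used, and each of 19938 symbols was represented by its probe set with the highest mean over all arrays. Genes whose mean lay below the 30th percentile of these probe sets (6.42) were left out, which left 13954 genes. Of these, 13913 matched a gene of the GRCm38.p6 reference table by identifier, and 0 of them had another symbol there. The number of arrays limits the precision, with 18 residual degrees of freedom in the model described next. The exact relations between arrays described below leave fewer free residuals than this, which the model does not account for. Its p-values and gene counts are therefore approximate.

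All 28 arrays entered 1 linear model in limma 3.58.1 (R 4.3.3; figures with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9). It had a coefficient for each of the 9 groups and a term for the PGKnvA vector, and variances were moderated with a mean-variance trend. Tests were two-sided and p-values were adjusted over the tested genes by the Benjamini-Hochberg method, with a gene called at an adjusted p under 0.05. Samples were grouped by the transgene and genotype labels, and nothing in the labels says that replicates came from separate cultures. The p-values therefore measure only the spread between these arrays, which may be technical. A contrast for the hotspot mutants took the mean of the 5 mutant groups with equal weights.

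Groups, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named Dicer1, then for each of 4 main comparisons the 8 genes with the largest rise and the 8 with the largest fall among those called, and up to 3 called members of each list by absolute change. For the other comparisons it took up to 4 genes each way. Symbols of predicted genes, miRNA and snoRNA genes, olfactory and vomeronasal receptors and immune receptor segments were left out of this rule, and miRNA probe sets were described as a list without the expression filter. One of the 8 largest falls between the parental lines, annotated with a sequence record in place of a symbol, is not reported here.

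The 20 fixed lists were pluripotency, primed epiblast and early ectoderm, mesoderm and primitive streak, endoderm, trophoblast, fibroblast or feeder markers, interferon response, two-cell-stage genes, germline genes, reported targets of the miR-290 and miR-302 family, of let-7 and of the miR-17 and miR-106 family, miRNA machinery, DNA methylation and silencing, p53 pathway and apoptosis, G1-S cell cycle, imprinted genes, extracellular matrix and adhesion, retinoic acid and Hox genes, and housekeeping controls. Older symbols were matched through the reference table unless the symbol is still in use for another gene. Lists were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over 80 tests, and again with an estimated correlation, with fry and against 10000 random lists matched on mean expression. Lists of seed matches in 3-prime untranslated regions had been planned and were not run, since untranslated-region sequences were not used here.

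A signature score of the Dicer-null state was the mean log2 of 200 genes higher in the Dicer-null than in the Dicer wild-type parental line minus that of 200 genes lower. It was compared between transgene groups, which did not define it, by exact permutation tests. Likeness of comparisons that share control arrays was set against 100 simulations of unchanged groups.

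The deposited values obey exact linear relations across arrays, found after the data were examined. Over all probe sets, 3 singular values of the deposited values across the arrays were at most 0.00233, while the next was 24.1. The deviations of array 4 of D1709A and array 4 of wild-type DICER1 from arrays 1 to 3 of their group summed to 0 within 1.33e-04. Those of the first arrays of 5 groups, from the mean of the arrays numbered 1 to 3 of their group, summed to 0 within 1.83e-04. The means of PGKnvA and ENvA wild-type arrays were equal within 7.5e-05. Such relations remain when fitted effects of array sets are subtracted, and the processing notes used here name no such step. The arrays were therefore also treated as 4 array sets: the first arrays of those 5 groups (set 1), the other ENvA and parental arrays (set 2), array 4 of both D1709A and wild-type DICER1 (set 3) and the PGKnvA arrays (set 4). Sets 1 and 2 were pooled in within-set comparisons, and the set of the eGFP vector and D1810Y arrays could not be read from the values, so these arrays entered no within-set comparison.

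Alternatives changed the expression filter, the vector term, the arrays in the fit, the variance trend, the normalisation, the weighting of the mutants and the replicate block, and left out each array in turn. Those built on the array sets were chosen after seeing the data. The scripts were tested on simulated data with the spread of the real arrays and 200 changed genes. The simulated arrays were independent, so the false calls below do not show the effect of the exact relations. For the mutants against wild-type DICER1, 83.6% of simulated changes of 0.25, 98.5% of those of 0.5 and 100% of those of 1 on the log2 scale were recovered, with 6 false calls among 194 over 13954 genes. For wild-type DICER1 against the eGFP vector the shares were 43.3%, 92.5% and 100%, with 15 false calls among 172. With each array set as 1 replicate they were 34.3%, 94.0% and 100%, with 0 false calls among 152. In the simulated list test the raised list was called at an adjusted p of 3.42e-114, and 0 other lists were called.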

Results

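DICER1 is the ribonuclease that excises mature microRNAs (miRNAs) from hairpin precursors, and its RNase IIIb domain makes the incision that frees the 5-prime strand. The series asked how hotspot mutations of that domain affect miRNA processing. Mouse ES cells lacking Dicer carried an eGFP vector (n = 3 arrays), wild-type DICER1 (n = 6) or a mutant DICER1, namely D1709A (n = 4), D1709N (n = 2), E1705K (n = 3), D1810Y (n = 3) or E1813Q (n = 2). The parental Dicer-null line (n = 3) and a Dicer wild-type line (n = 2) were profiled without a transgene. D1709N, E1813Q and 2 of the wild-type DICER1 arrays used the PGKnvA lentiviral vector, and the other transgenes used ENvA. Levels below are log2 expression values, and the median standard deviation of a gene within a group ranged from 0.0450 to 0.0891. No background level was measured, so no size of change is given below where the mean of a compared group lay under 6.42, the level of the expression filter.

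Dicer1 was the targeted gene and was examined first. Its probe set read 10.68 ± 0.05 (SD, n = 2) in the Dicer wild-type line and 9.27 ± 0.04 (n = 3) in the Dicer-null line, a fall by 1.41 (SE, 0.0683, adjusted p = 3.52e-15 in limma). It read 9.39 ± 0.10 (n = 3) with the eGFP vector, 9.31 ± 0.07 (n = 6) with wild-type DICER1, and between 8.91 and 9.30 in the mutant groups. The labels do not state the species of the transgene, and whether this mouse probe set reads it is not given in the sources used here. Transgene levels were therefore not compared between groups.

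The parental lines were compared next, and with 1 line named for each genotype, other differences between the lines are not separated from the loss of Dicer. In Dicer-null cells the reported targets of the miR-290 and miR-302 family, the dominant miRNAs of mouse ES cells, were higher than in Dicer wild-type cells. Of 21 measured targets, 18 rose and 1 fell, among them Lefty1, a Nodal antagonist (2.31), Tgfbr2, a TGF-beta receptor (1.87), Btg2, an antiproliferative gene (1.80), Lats2, a Hippo pathway kinase (1.79), and Rbl2, a retinoblastoma-related repressor (1.30). Tbx20, Msln, Pla2g7 and Ccdc141 rose between 9.75-fold and 13.6-fold, and Cd109, Irgm1, an interferon-inducible GTPase, Hivep2 and Adh7 rose from levels under 6.42. Dnmt3l, a cofactor of the de novo DNA methyltransferases, fell by 3.11, Lin28a, which blocks let-7 maturation, fell by 2.35, and Sfmbt2, which hosts a miRNA cluster in an intron, fell by 2.81. Dppa3, the imprinted non-coding RNA Meg3 and Usp51 fell to levels under 6.42. Prelid2 (-2.96) and Rragb (-2.83) fell as well, and the carbonic anhydrase Car4 fell from 9.74 ± 0.02 (SD, n = 2) to 6.74 ± 0.18 (n = 3).

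In the same comparison, 18 of 23 measured matrix and adhesion genes rose and 1 fell, with Thbs1 2.66, Vim 2.28 and Cdh2 2.06 higher, and fibroblast or feeder markers rose in 4 of 14 cases and fell in 1 (camera adjusted p = 0.675). Of 20 p53 pathway genes 16 rose and 0 fell, including Casp2 (1.42), Perp (1.38) and Pmaip1 (1.05). Among 24 G1-S genes 13 rose and 1 fell, with Ccnd2, a D-type cyclin, 2.45 higher, and among 19 reported targets of the miR-17 and miR-106 family 12 rose and 1 fell. By camera, adjusted p was 1.4e-05 for the miR-290 and miR-302 targets, 2.37e-06 for matrix genes, 5.51e-04 for the p53 list, 0.0132 for G1-S genes and 0.0132 for miR-17 and miR-106 targets. With an estimated correlation the adjusted p was 0.0202 for the first list and 0.0202 for the matrix list, and 0.343, 0.114 and 0.194 for the p53, G1-S and miR-17 lists. Adjusted over the list alone, the counts were the same except that 2 of the miR-290 and miR-302 targets fell. Trophoblast genes rose in 3 of 10 cases and fell in 2 (camera adjusted p = 0.973). Imprinted genes rose in 6 of 21 and fell in 10 (0.487), and pluripotency genes rose in 9 of 28 and fell in 11 (0.172). In all, 8074 of 13954 genes were called, 4282 higher and 3792 lower in Dicer-null cells, and 649 and 320 of them changed at least 2-fold. With each array centred on its median the split was 5232 and 2893.

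Re-expression of wild-type DICER1 in Dicer-null cells was compared with the eGFP vector to find the genes that the enzyme changes. Lefty1 fell by 2.61, Lefty2 by 2.30, Bmi1, a Polycomb gene, by 1.11 and Rbl2 by 0.94, and 15 of the 21 miR-290 and miR-302 targets fell while 3 rose. Dppa3, Dnmt3l and Lin28a, which were low in the Dicer-null line, rose by 2.48, 2.21 and 1.65. The pluripotency list that holds them went both ways, with 12 of 28 genes higher and 11 lower (camera adjusted p = 0.649). Ccnd2 fell by 2.09 and Ccnd1 by 1.23. The largest rises were Bnip3, a hypoxia-inducible mitochondrial gene (9.67-fold), Elobl (9.31-fold), Car4 (8.67-fold), Prelid2 (8.18-fold), the smooth muscle actin Acta2 (6.71-fold), Pla2g1b (6.47-fold) and Kdelr3 (5.74-fold), and the meiotic gene Sycp3 rose from a level under 6.42. The largest falls were the keratin Krt17 (-3.29), Msln (-3.10), Pof1b (-3.06), Ido2 (-2.90), Fetub (-2.90), Ccdc141 (-2.86) and Apobec2 (-2.66), and Ube2dnl1 fell to a level under 6.42.

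Trophoblast genes, not called as a list between the parental lines, rose with wild-type DICER1 in 8 of 10 cases and fell in 0. Among them were Bmp4 (1.55), Eomes (1.33) and Gata3 (1.17). The camera adjusted p was 0.0383 for this list and 4.64e-04 for the miR-290 and miR-302 targets. The adjusted p with an estimated correlation was 0.343 and 0.0535, so both calls were lost. Counts adjusted over the list alone were the same for both lists. In total 8307 genes were called, 4301 higher and 4006 lower (3788 and 4395 with each array centred on its median), of which 210 and 311 changed at least 2-fold. Among 11 housekeeping controls 4 rose and 4 fell, with Pgk1 0.96 higher, and the markers of fibroblasts or feeders rose in 8 of 14 cases and fell in 1 (camera adjusted p = 0.0867, and 0.00291 against matched random lists).

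**Figure D1:**
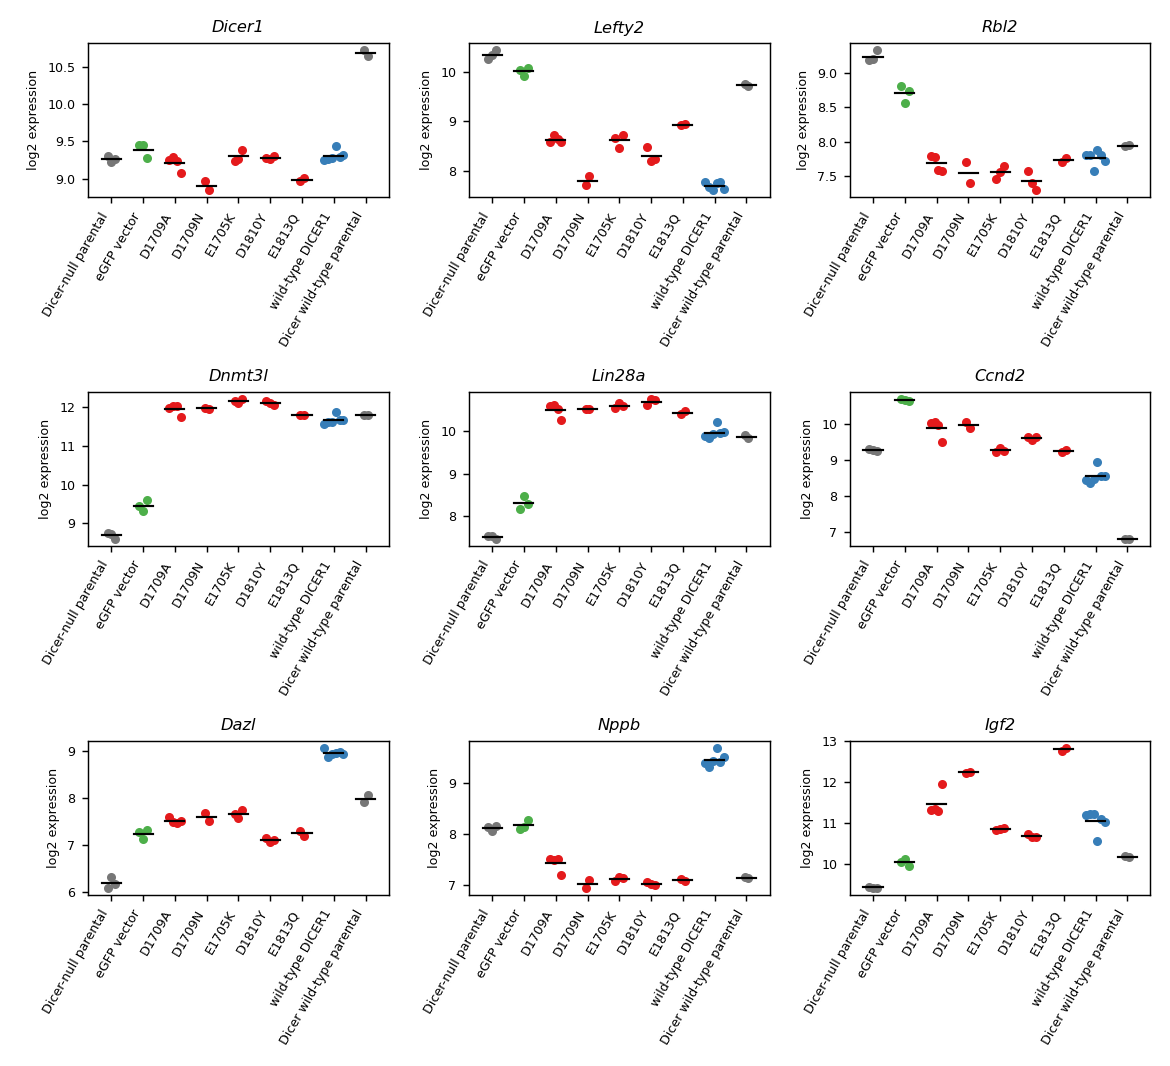
Log2 expression of 9 genes in each of the 28 arrays (points) by group, with group means as lines. Dicer1 separates the Dicer wild-type line (10.68) from all other groups, and Nppb reads 9.47 with wild-type DICER1 against 7.03 to 7.44 with the mutants.

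The mutants were then set against the eGFP vector to see what mutant DICER1 still changed. Dppa3 (2.54), Dnmt3l (2.54) and Lin28a (2.22) rose, as did Car4 (18.6-fold), Elobl (8.06-fold), Pla2g1b (7.92-fold) and Acta2 (7.18-fold), and the protease inhibitor Spink1 rose from a level under 6.42. The falls were led by Pla2g7 (-3.39), Pof1b (-2.93), Ccdc141 (-2.92), Msln (-2.87), Krt17 (-2.70), Ido2 (-2.57) and the Fc receptor Fcgr2b (-2.51), and Ube2dnl1 fell to a level under 6.42. Pluripotency genes rose in 7 of 28 cases and fell in 13 (camera adjusted p = 0.19). Among the 21 miR-290 and miR-302 targets 15 fell and 2 rose, with Lefty2 lower by 1.55 (log2 change, -1.55), Bmi1 -1.12 and Rbl2 -1.12. All 10 trophoblast genes rose, among them Bmp4 (1.36), Ascl2 (1.23) and Hand1 (0.82). Fibroblast or feeder markers rose in 5 of 14 cases and fell in 2, with Tagln 1.16 and Pdgfrb 0.98 higher (camera adjusted p = 0.315, and 0.00343 against matched random lists). Of 21 imprinted genes 14 rose and 2 fell, with Sgce 1.89, Phlda2 1.74 and Igf2 1.56 higher. Camera gave an adjusted p of 1.4e-05 for the targets, 5.16e-04 for trophoblast genes and 3.07e-04 for imprinted genes. With an estimated correlation the adjusted p was 0.0202, 0.0907 and 0.0202. The counts adjusted over the list alone were the same for these 3 lists, and 7406 genes were called (4090 higher and 3316 lower, or 3526 and 3830 with each array centred on its median, with 156 and 187 changed at least 2-fold).

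**Figure D2:**
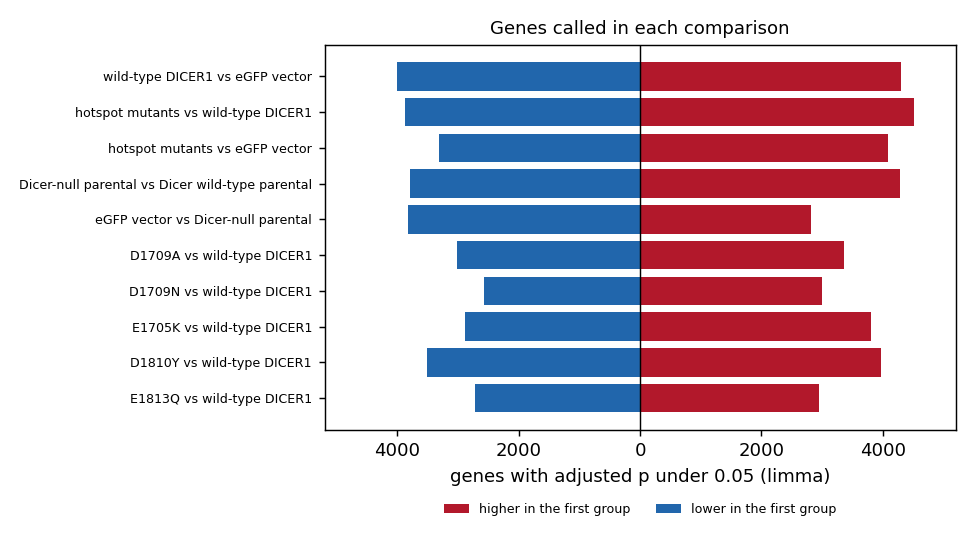
Number of genes called by limma (adjusted p under 0.05) in each comparison, drawn to the right where higher and to the left where lower in the first group named. The hotspot mutants against wild-type DICER1 gave 4512 higher and 3870 lower genes.

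Against wild-type DICER1, the mutants kept Lefty1 higher by 1.53 and Lefty2 by 0.75 on the log2 scale, and Ccnd2 and Ccnd1 were higher by 1.04 and 1.02. Lefty1 averaged 8.93 ± 0.24 (SD, n = 6) with wild-type DICER1, between 10.27 and 10.63 in the 5 mutant groups and 11.55 ± 0.05 (n = 3) with the eGFP vector. The de novo methyltransferases Dnmt3b and Dnmt3a rose by 1.11 and 0.82. The other large rises were Fndc3c1 (3.29-fold), the iron exporter Slc40a1 (2.95-fold), the fatty acid transporter Slc27a2 (2.91-fold), the endocytic receptor Lrp2 (2.85-fold), the potassium channel Kcnj3 (2.69-fold) and the vitamin C transporter Slc23a1 (2.62-fold), and Spink1 rose from a level under 6.42. The largest falls were A2m, a protease inhibitor (-2.32), Nppb, a natriuretic peptide (-2.32), Nab2, a corepressor of EGR factors (-2.04), Phlda1 (-1.84) and Prelid2 (-1.58). Next were serglycin Srgn (-1.57), the germ cell RNA-binding gene Dazl (-1.53) and the growth factor Hbegf (-1.52). Within array sets 1 and 2, 3 and 4, Srgn changed by -0.50, -2.47 and -2.80, so its fall was uneven among the mutants. Nppb was 8.18 ± 0.09 (n = 3) with the eGFP vector and 9.47 ± 0.13 (n = 6) with wild-type DICER1, and it lay between 7.03 and 7.44 in the mutant groups, below both.

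Of 21 imprinted genes 15 rose and 2 fell in the mutants, with Ascl2 1.37, Mest 0.92 and Nnat 0.79 higher and Igf2r 0.30 lower (log2 change, -0.30). Germline genes fell in 10 of 15 cases and rose in 3, with Dazl (-1.53), Sycp3 (-1.16) and Tex19.1 (-0.87) falling most. The camera adjusted p was 0.00481 for imprinted and 0.0371 for germline genes, and with an estimated correlation the adjusted p was 0.0533 and 0.412, so that both calls were lost. The reported targets of miRNAs moved both ways. Of the miR-290 and miR-302 targets 8 rose and 10 fell (adjusted p = 0.81), of 20 let-7 targets 11 rose and 6 fell (0.305), and of the miR-17 and miR-106 targets 8 rose and 7 fell (0.977). Against matched random lists the adjusted p was 0.727, 0.0261 and 0.369 for these target lists. Adjusted over the list alone, the counts of these 5 lists were the same. Within array sets 1 and 2, 3 and 4, the median change of the imprinted list was 0.22, 0.08 and 0.24, that of the germline list was -0.21, -0.50 and -0.35, and that of the let-7 list was 0.13, -0.17 and 0.10.

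The other fixed lists were not called by camera in this comparison. Pluripotency genes rose in 9 and fell in 17 of 28 cases, with Tbx3 (-0.83) and Tcl1 (-0.70) lower and Utf1 (0.70) higher (adjusted p = 0.0557). Primed epiblast genes rose in 8 and fell in 3 of 17 (0.368), mesoderm genes in 6 and 3 of 18 (0.759), and trophoblast genes in 6 and 2 of 10 (0.497). Endoderm genes rose in 5 and fell in 7 of 20, with Gata6 lower by 0.82 (log2 change, -0.82) (0.496). Fibroblast or feeder markers rose in 1 and fell in 5 of 14 (0.335), interferon genes in 3 and 1 of 12 (0.34), and two-cell-stage genes in 0 and 1 of 5 (0.497). The miRNA machinery list rose in 9 and fell in 6 of 21 (0.706), and DNA methylation genes in 10 and 8 of 21 (0.706). For p53 genes the counts were 3 and 9 of 20 (0.172), for G1-S genes 10 and 6 of 24 (0.564), for matrix genes 8 and 9 of 23 (0.564), for retinoic acid and Hox genes 3 and 0 of 11 (0.564) and for housekeeping controls 4 and 5 of 11 (0.892). Adjusted over the list alone, 8 endoderm genes and 10 matrix genes fell, 5 housekeeping controls rose and the other counts were the same.

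In total 8382 genes were called between the mutants and wild-type DICER1, 4512 higher and 3870 lower, of which 60 and 42 changed at least 2-fold. Every mutant array lay above every wild-type DICER1 array for 1252 genes and below for 1123. Exchangeable arrays would give 0.00258% of genes each way, but the array sets and exact relations mean that these arrays are not exchangeable. Within the 3 array sets that hold both genotypes, 6395 of the 13954 tested genes (45.8%) had 1 sign throughout. No share by chance is given, because the wild-type mean of set 4 equals that of the wild-type arrays in the other sets, so that the 3 differences are not independent. Lefty1 was higher by 1.28, 2.31 and 1.51 in sets 1 and 2, 3 and 4, and Nppb changed by -2.07, -2.49 and -2.40. Slc40a1 (2.37, -0.39 and 0.88) and Lrp2 (1.93, -0.22 and 1.10) changed sign in set 3. With each array set as 1 replicate, 164 genes were called (79 higher, 85 lower), all of which were also called with the same sign over the 28 arrays, but the dependence between the sets makes these p-values approximate. Of the genes named above for this comparison, Fndc3c1, Slc40a1, Slc27a2, Lrp2, Prelid2, Srgn, Ccnd2, Ccnd1, Dnmt3a, Dnmt3b, Ascl2, Mest, Nnat, Tbx3, Tcl1 and Utf1 were not among these 164.

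The likeness of the mutant and wild-type responses was measured across genes, which are not independent replicates. Of 521 genes changed at least 2-fold by wild-type DICER1, the mutants were called different from both the eGFP vector and wild type and lay between them for 360. They were not called different from wild type for 88, and for 27 they were called different from wild type and not from the eGFP vector. They lay beyond wild type for 40 and beyond the eGFP vector for 6, Nppb among them. The median ratio of the mutant to the wild-type change was 0.726 (quartiles 0.507 and 0.909). These genes were selected on the same eGFP and wild-type arrays, which favours mutants in between, and the slope over all 13954 genes was 0.666. Genes raised by both numbered 2829, where independent lists would share 1260.6, and genes lowered by both numbered 2493, where they would share 952.0. Both lists rest on the same eGFP arrays, which by itself raises the overlap, and no overlap of unchanged groups was simulated. The fold changes correlated with r = 0.783, and the covariance was 0.130. Unchanged groups, simulated with the spread within groups and a shared simulated eGFP group, gave r = 0.737 and a covariance of 0.00367. Comparisons that share no array, with the Dicer-null line as the other control, gave r = 0.553 and 0.666. They are still not independent, since the equal wild-type means of both vectors tie the PGKnvA mutants to the wild-type arrays.

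A signature score placed each array between the parental lines. The score was 2.16 ± 0.01 (SD, n = 3) in the Dicer-null line and -1.48 ± 0.03 (n = 2) in the Dicer wild-type line, which define it. It was 1.35 ± 0.01 (n = 3) with the eGFP vector and -0.57 ± 0.10 (n = 6) with wild-type DICER1, a difference of -1.93 (exact permutation p = 0.0119, adjusted 0.0298, the smallest that 84 splits allow). Mutant arrays averaged -0.22 ± 0.15 (n = 14), or -1.57 from the eGFP vector (exact permutation p = 0.00147, adjusted 0.011, the smallest possible) and 0.35 from wild-type DICER1 (exact permutation p = 1.03e-04, adjusted 0.00155). The mutant difference from wild type was 0.33 within ENvA arrays (exact permutation p = 0.00699) and 0.42 within PGKnvA arrays, where no p under 0.0667 is possible. The wild-type mean was -0.57 with either vector, since the deposited means of these arrays are equal, so both differences are not independent. Within array sets 1 and 2, 3 and 4 the mutant difference was 0.39, 0.07 and 0.42. The score fell by more than any of these from the Dicer-null to the eGFP line. Differences of this size thus also arose between lines without a DICER1 transgene. By mutant, the score was -0.12 ± 0.13 for D1709A (n = 4), -0.11 ± 0.01 for D1709N (n = 2), -0.45 ± 0.04 for E1705K (n = 3), -0.23 ± 0.02 for D1810Y (n = 3) and -0.19 ± 0.01 for E1813Q (n = 2). E1705K differed from wild-type DICER1 by 0.13 (exact permutation p = 0.107, adjusted 0.107). In this test against wild-type DICER1 the adjusted p was 0.0238 for D1709A and 0.0298 for D1810Y. It was 0.0595 for D1709N and for E1813Q, whose unadjusted p of 0.0357 was the smallest possible. The 15 score tests formed 1 family, all two-sided. They permuted single arrays, several per transgene, and the array sets and exact relations mean that these arrays are not exchangeable. Their p-values are therefore approximate.

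**Figure D3:**
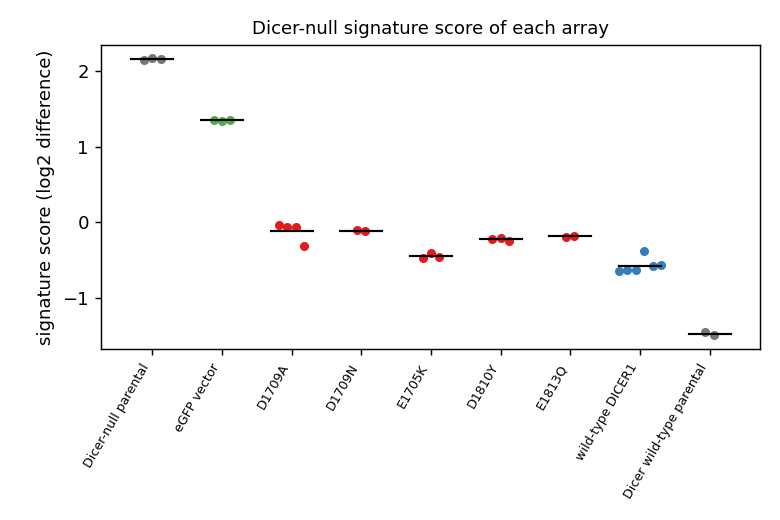
Dicer-null signature score of each array (points; log2 difference of 200 higher and 200 lower genes) by group, with group means as lines. The mutants average between -0.45 and -0.11, wild-type DICER1 -0.57 and the eGFP vector 1.35.

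Each mutant was also compared with wild-type DICER1. A2m and Nppb were among the 4 largest falls with all 5 mutants, A2m changing between -2.14 and -2.46 and Nppb between -2.03 and -2.44. Nab2 was among them with D1709A (-2.01), E1705K (-2.40) and D1810Y (-2.30), Phlda1 with D1709N (-1.87), E1705K (-2.14) and E1813Q (-2.19), and Prelid2 with D1709A (-1.73) and D1810Y (-2.06). The rises were led by Spink1 with D1709A (8.26 ± 0.17, SD, n = 4, against 6.21 ± 0.15, n = 6), the neurogenic factor Neurod1 with D1709N (3.33-fold), Slc40a1 with E1705K (4.81-fold), the carbonic anhydrase Car3 with D1810Y (5.60-fold) and Igf2 with E1813Q (3.33-fold). Slc27a2 and Fndc3c1 rose with E1705K (4.09-fold and 4.23-fold) and D1810Y (5.00-fold and 4.90-fold), and Dapp1 with D1709N (2.74-fold) and E1813Q (2.92-fold). Genes called numbered 6392 for D1709A (3366 higher, 3026 lower), 5576 for D1709N (2995 and 2581), 6699 for E1705K (3810 and 2889), 7500 for D1810Y (3980 and 3520) and 5661 for E1813Q (2942 and 2719, or 2481 and 3067 with each array centred on its median).

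The mutants differed among themselves in 6073 genes by a moderated F test. Igf2 read 12.24 ± 0.02 (SD, n = 2) with D1709N and 12.79 ± 0.05 (n = 2) with E1813Q, against 10.86 ± 0.02 (n = 3) with E1705K and 10.68 ± 0.05 (n = 3) with D1810Y (adjusted p of any difference, 1.87e-07 in limma). Srgn read 5.62 ± 0.31 (n = 2) with D1709N and 5.79 ± 0.28 (n = 2) with E1813Q, and 8.47 ± 0.20 (n = 3) with E1705K (adjusted p of any difference, 2.96e-08). Pairs of mutants differed in 706 genes (D1709A and D1709N) to 3937 genes (D1810Y and E1813Q). D1709N and E1813Q are the PGKnvA mutants, and the vector or array set of these arrays cannot be told apart from the mutation when they are set against the others. With ENvA and parental arrays alone, 3974 genes differed among the remaining 3 mutants.

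Hairpin probe sets of miRNA genes, which can read precursor or host transcripts and not mature miRNAs, were described as a list of 300, of which 112 passed the expression filter. Against wild-type DICER1, 33 rose and 37 fell in the mutants (30 and 34 when adjusted over the list alone). The 4 probe sets of the miR-302 cluster rose (adjusted p = 1.03e-13 for Mir302b in limma), Mir363 rose by 1.62 and Mirlet7f-1 fell (adjusted p = 3.29e-11). Mean levels of the 4 miR-302 probe sets were 4.99 ± 0.44 (SD, n = 6) with wild-type DICER1, 7.41 ± 0.28 (n = 3) with the eGFP vector, 8.74 ± 0.19 (n = 3) with D1810Y and between 6.90 and 7.11 with the other mutants. They were 5.40 ± 0.05 (n = 3) in the Dicer-null and 5.49 ± 0.13 (n = 2) in the Dicer wild-type line. Between the parental lines 10 hairpin probe sets were higher and 67 lower in Dicer-null cells (6 and 58 when adjusted over the list alone), among the latter Mir377 (3.64 ± 0.07, n = 3, against 6.95 ± 0.20, n = 2, adjusted p = 1.73e-20) and Mir382 (4.31 ± 0.17 against 6.56 ± 0.29, adjusted p = 1.23e-14), both of the Meg3 locus.

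**Figure D4:**
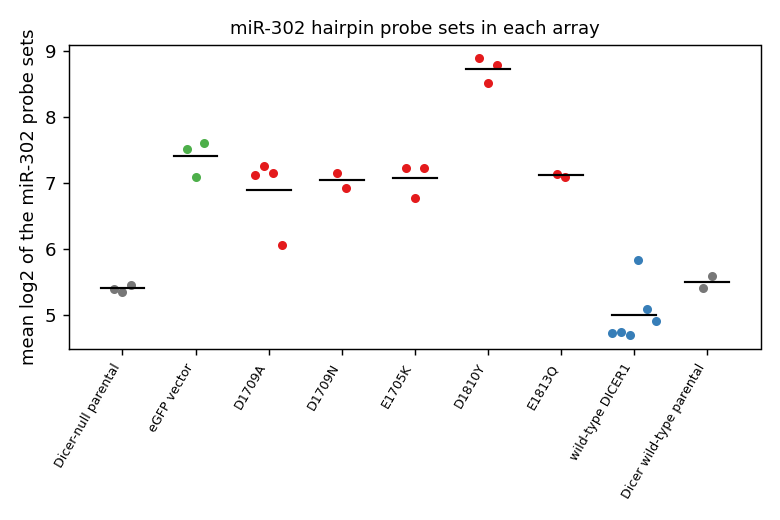
Mean log2 level of the 4 miR-302 hairpin probe sets in each array (points) by group, with group means as lines. Wild-type DICER1 averages 4.99, the eGFP vector 7.41 and D1810Y 8.74.

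Transduction with the eGFP vector served as the background for the transgene comparisons. The immediate early genes Fos, Fosb and Atf3 fell by 3.52, 2.11 and 1.96 from the Dicer-null line, and Acss1 fell by 1.90. Atrx, a chromatin remodeller, rose 4.74-fold, Kif20b and Cenpe rose 4.33-fold and 4.28-fold, and Cep290 rose from a level under 6.42. In all 6644 genes were called, 2822 higher and 3822 lower, with 159 and 108 changed at least 2-fold, and with arrays centred on the median the split was 2152 and 4896. The eGFP line thus differed from its parent in numbers of genes close to those of the DICER1 comparisons. Between PGKnvA and ENvA wild-type DICER1 arrays, limma called 0 genes and 0 had an unadjusted p under 0.05, because the deposited means of these arrays are equal.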

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

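The tests of array-set removal and of a label swap below were chosen after the result was seen, and the counts over other splits of the arrays were planned.

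Array 4 of D1709A and array 4 of wild-type DICER1 stood far from the other arrays of their groups for many of the measures named here. By Dixon's test at its 95% limit, 88 of the tested groups of values held an array apart from the rest, where chance gives 1 in 20 or about 15.1, and the array was number 4 in all 88 (43 in D1709A and 45 in wild-type DICER1). The values below are the gap of that array to its nearest neighbour as a share of the whole range. In D1709A these gaps were Bnip3 0.962, Prelid2 0.859, Dppa3 0.945, Dnmt3l 0.835, Cdh2 0.855, Fgf15 0.943, Bmp4 0.910, Eomes 0.879 and Tagln 0.912 of the range. For a further set of D1709A measures they were Oas1a 0.853, Arg2 0.889, Ccnd2 0.847, Dnmt3b 0.881, Perp 0.876, Bcl2l11 0.892, Sesn2 0.948, Myc 0.919 and Ccn1 0.928. Array 4 of D1709A also stood apart for Slc40a1 0.871, Lrp2 0.902, Nppb 0.931, Nab2 0.969, Phlda1 0.897, Srgn 0.949, Utf1 0.858, Ascl2 0.924 and Krt8 0.912. Then came Fn1 0.849, Arid4b 0.928, Thbs1 0.922, Pmaip1 0.971, Mycn 0.880, Mest 0.980, Crabp2 0.831, Pla2g7 0.877 and Pax6 0.839. The remaining D1709A gaps were Igf2 0.930, Rragb 0.876, Sfmbt2 0.867, Vim 0.830, Car3 0.871, the signature score 0.883 and the miR-302 probe sets 0.883.

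In wild-type DICER1 the gaps were Dicer1 0.655, Bnip3 0.727, Prelid2 0.688, Acta2 0.684, Kdelr3 0.638, Krt17 0.662, Dnmt3l 0.672, Lin28a 0.651 and Bmp4 0.708 of the range. Others in this group were Eomes 0.704, Dab2 0.632, Gata3 0.640, Tagln 0.726, Ccnd2 0.636, Ccnd1 0.676, Dnmt3b 0.702, Bcl2l11 0.657 and Sesn2 0.645. Array 4 of wild-type DICER1 stood apart as well for Myc 0.692, Meis2 0.638, Pgk1 0.699, Fndc3c1 0.698, Slc40a1 0.713, Lrp2 0.699, A2m 0.629, Nab2 0.652 and Srgn 0.655. Next were Utf1 0.693, Ascl2 0.688, Krt8 0.690, Fn1 0.693, Oasl2 0.639, Thbs1 0.722, Casp2 0.626, Mycn 0.703 and Mest 0.675. The last gaps of this group were Pla2g7 0.720, Igf2 0.667, Irgm1 0.666, Sfmbt2 0.652, Vim 0.725, Kif20b 0.680, Acss1 0.634, the signature score 0.713 and the miR-302 probe sets 0.653.

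The deviations of both arrays from arrays 1 to 3 of their groups cancelled, with a largest absolute sum of 1.33e-04 over all probe sets, which is what the removal of array-set effects before deposit leaves. An effect subtracted from both arrays leaves their difference as it was, so it gives no cause for the departure of the D1709A effect in array 4 from that in arrays 1 to 3, seen in 7472 of 13954 genes by an interaction term. As the deviations mirror each other, this term restates them and is no separate evidence. With 1 array of each genotype numbered 4 and the form of the adjustment not given in the sources used here, a share of it in this departure cannot be told apart. If the labels of these 2 arrays had been swapped, the difference of D1709A from wild-type DICER1 in array 4 would run against that in arrays 1 to 3, and its correlation across genes, which are not independent replicates, was 0.0940. No biological explanation was tested.

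The 5 mutants differed among themselves in 6073 genes by a moderated F test.

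Other splits of the same arrays bear on the gene counts. For wild-type DICER1 against the eGFP vector, 1 of 84 splits, the real one, reached its 8307 genes. The split that parted wild-type arrays 1 to 3 from the rest gave 7068. The vector term was kept in each split and took up wild-type arrays 5 and 6 there. That split thus set wild-type arrays 1 to 3 against the eGFP arrays and wild-type array 4, which is close to the real comparison. For the mutants against wild-type DICER1, 1 of 100 splits reached the real count of 7545 (the 14 mutant arrays as 1 group, highest other 1016). Against the eGFP vector 1 of 100 reached 6931 (highest other 2113). The real split alone also reached its count for D1709A (1 of 100 splits, 6392 genes, highest other 4818), E1705K (1 of 84, 6699, highest other 6113) and D1810Y (1 of 84, 7500, highest other 7035). Arrays of 1 line may group together whatever its transgene, so these splits cannot exclude chance differences between lines. The highest other splits of E1705K and D1810Y grouped the mutant arrays with wild-type arrays 4 to 6. There too the vector term took up wild-type arrays 5 and 6, which left comparisons close to the real ones. That of D1709A grouped the mutant arrays with wild-type arrays 4 and 5. For the eGFP vector against the Dicer-null line, the 10 splits are too few for a share under 0.05 (real 6644, reached by 1 split, highest other 0).

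Chance was not excluded for the number of fixed lists called by camera. As many lists as with the real groups were called in 56 of 84 splits for wild-type DICER1 against the eGFP vector (real 1, highest other 7), in 52 of 100 for the mutants against wild-type DICER1 (real 2, highest other 7) and in 44 of 100 for the mutants against the eGFP vector (real 3, highest other 10). Here list p-values were adjusted within each comparison, over the 20 lists, and not over the 80 list tests of the report, so the real numbers can differ from those given there.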

How the results depend on the processing

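The alternatives built on the array sets (both arrays numbered 4 left out, the array set as a covariate, and each array set as 1 replicate) were chosen after the data were seen, and the others were planned. Of the values of single named genes under the alternatives, 11756 kept direction and side of the threshold, 60 became weaker, 1 became stronger (Dicer1 in wild-type DICER1 against the eGFP vector, -0.13 with both arrays numbered 4 left out) and 2 reversed. Most of the weaker values came from each array set as 1 replicate, where most genes named for the mutants against wild-type DICER1 lost their call. The reversed values, both for the mutants against wild-type DICER1, were Hand1 at -0.0248 with ENvA and parental arrays only and Pdgfrb at 0.12 with PGKnvA mutants only, where fewer mutants enter. Of the list results, 490 kept direction and call, 62 became stronger, 8 weaker and 0 reversed. With an estimated correlation 4 of the 80 list tests were called, with fry 62 and against matched random lists 23, against 12 with the preset correlation, and the cause was not tested.

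The count of genes that differ among the mutants was 3974 with ENvA and parental arrays only, where 3 mutants remain, 3854 with a replicate block, 8551 with both arrays numbered 4 left out and 8948 without the vector term. The block also lowered the counts of D1709N to 3470 and of E1813Q to 3562, and the cause was not tested. The labels do not say that replicate numbers pair the arrays. Same-number deviations of different groups correlated across genes from -0.691 to 0.467, from -0.572 to 0.684 and from -0.488 to 0.317 for numbers 1 to 3 (medians -0.0424, -0.00638 and -0.0183). The single pair numbered 4 mirrored each other, and the first-array deviations of 5 groups sum to 0. Such exact relations shape these correlations, which therefore do not show that pairing is absent. With both arrays numbered 4 left out, 5 genes were called between PGKnvA and ENvA wild-type DICER1, because the exact equality of these means no longer held. With each array set as 1 replicate, 164 genes were called for the mutants against wild-type DICER1, where 3 within-set differences are the replicates and D1810Y does not enter. These differences are not independent, since the wild-type mean of set 4 equals that of the wild-type arrays in the other sets.

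Leaving out each array in turn gave 7630 to 8587 genes for wild-type DICER1 against the eGFP vector, 7675 to 8689 for the mutants against wild-type DICER1, 6605 to 7780 for the mutants against the eGFP vector, 6911 to 8411 for the parental lines, 5994 to 6965 for the eGFP vector against the Dicer-null line and 0 in each run for PGKnvA against ENvA. The ranges were 5706 to 6907 for D1709A, 4108 to 6054 for D1709N, 5996 to 7188 for E1705K, 6716 to 7957 for D1810Y, 4193 to 6073 for E1813Q and 5170 to 7573 for any difference among mutants. A group left with 1 array was assumed to vary like the others. Score differences ranged from -1.96 to -1.87, from -1.59 to -1.53 and from 0.34 to 0.39. No value could be had for PGKnvA against ENvA without the vector term or with ENvA arrays only, nor for D1709N and E1813Q with ENvA arrays only. Planned seed target lists and scores were not run. Genes with means under 6.42 did not enter the gene counts, while miRNA probe sets under it were tested as a list, and no background level was measured here.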

Other observations

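The tests of unprocessed hairpins, of a shift of all hairpin probe sets, of the shared eGFP arrays and of the miRNA strands below were chosen after the result was seen, and those of the primed epiblast state and of drift were planned.

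Meg3 and the hairpin probe set Mir377 of the same imprinted locus were low in every line derived from the Dicer-null cells. Meg3 read between 6.29 and 6.52 in the 8 Dicer-null-derived groups and 9.41 ± 0.06 (SD, n = 2) in the Dicer wild-type line, and neither wild-type DICER1 (adjusted p = 0.570 in limma) nor the mutants (adjusted p = 0.813) were called different from the eGFP vector. Mir377 read between 3.62 and 3.94 in those groups and 6.95 ± 0.20 (n = 2) in the Dicer wild-type line. The imprinted genes Phlda2 and Plagl1 did change with the transgene. Phlda2 was 1.84 lower (log2 change, -1.84) in Dicer-null than in Dicer wild-type cells and rose by 1.76 with wild-type DICER1 and by 1.74 with the mutants, while Plagl1 was 2.95 higher in Dicer-null cells and fell by 1.28 and 1.17.

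Interferon response genes were higher in Dicer-null cells for 6 of 12 members and lower for 3, with Zbp1 2.02 and Oas2 1.91 higher, but the list was not called by camera (adjusted p = 0.201). With wild-type DICER1, 7 of the 12 fell and 2 rose (adjusted p = 0.183), Zbp1 by 1.04 (log2 change, -1.04) and Oas2 by 0.74 (log2 change, -0.74). Among 15 germline genes 9 rose and 4 fell with wild-type DICER1 (adjusted p = 0.201). Adjusted over the list alone, these counts were the same.

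The miR-302 hairpin probe sets were higher in all 3 eGFP and all 14 mutant arrays than in each of the 6 wild-type DICER1 arrays. Unprocessed hairpins wherever Dicer is absent were excluded as the whole cause, since all 3 arrays of the Dicer-null line, which lacks Dicer as the eGFP line does, read under the filter level of 6.42 and the lowest of the 3 eGFP arrays read 0.665 above it. A shift of all hairpin probe sets was excluded, since the median of the other 109 that passed the expression filter differed by -0.0586 (95% interval, -0.0848 to -0.00909) between the eGFP vector and wild-type DICER1. A shift towards a primed epiblast state was predicted to raise its list in the eGFP vector and the mutants over wild-type DICER1. The list was not called in either comparison (camera adjusted p = 0.960 and 0.368), so the planned prediction was not met. Its members went both ways (6 rose and 5 fell with wild-type DICER1, 8 rose and 3 fell in the mutants), so a shift in part of them is not excluded. A change in transcription of the locus after transduction may be another candidate explanation, and it was not tested.

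The changes with mutant and wild-type DICER1 against the eGFP vector were alike across genes, which are not independent replicates. Spread between arrays within groups, carried by the shared eGFP arrays, was excluded as the whole cause. The covariance was 0.130 and the highest of 100 simulated values was 0.00385. The simulation drew independent arrays with that spread only, so it does not cover an offset of the eGFP line as a whole. Drift of the eGFP line alone would leave changes that share no array with little correlation, and these gave r = 0.553. The equal wild-type means of both vectors tie the PGKnvA mutants to the wild-type arrays in these values. Both changes are therefore not independent, so this value argues against drift alone without excluding it. Splitting the controls gave r between 0.713 and 0.765. A candidate explanation is that mutant DICER1 kept part of the activity of wild-type DICER1, but effects common to lines carrying any DICER1 transgene could not be separated from it.

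A hypothesis was that RNase IIIb mutants lose 5-prime strand miRNAs and keep 3-prime strands, so that targets of 5-prime strands would rise more. The mean change of 35 members of the 5-prime lists was 0.09 and that of 19 members of the 3-prime list was 0.04, with 2 shared genes left out. The difference of 0.04 gave a two-sided permutation p of 0.724 with 100000 resamples, and within array sets 1 and 2, 3 and 4 it was 0.14, -0.23 and -0.02. The 5-prime lists pooled let-7 targets with miR-17 and miR-106 targets. The seed of the latter family shares the letters AAGUGC with that of miR-302, which can blunt this contrast. Of the let-7 list alone the mean change was 0.18, called against matched random lists (adjusted p = 0.0261) and not by camera (adjusted p = 0.305). With wild-type DICER1 against the eGFP vector, 7 of the 20 let-7 targets rose and 8 fell. That change was called neither by camera (adjusted p = 0.808) nor against matched random lists (0.316). A list not called with the wild-type enzyme may not show a loss of its activity. The pooled lists thus showed no such difference here, which does not exclude one in the miRNAs themselves.

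Within-set changes of the mutants against wild-type DICER1 correlated across genes with r = 0.134 between sets 1 and 2 and set 3, 0.644 between sets 1 and 2 and set 4, and 0.629 between sets 3 and 4. The wild-type mean of set 4 equals that of the wild-type arrays in the other sets, so the last 2 pairs in effect share controls, and no value without change was computed for them. Median changes of the autosomes lay between -0.0687 and 0.117 over 5 comparisons and 13505 genes, where an additional copy of a chromosome would give 0.585.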
